A study of Homo sapiens with 6 samples.

How the data were processed

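The data were 6 Affymetrix HG U133 A 2.0 arrays of total RNA, 3 of HT29 cells sensitive to methotrexate and 3 of HT29 cells resistant to it, grouped by their titles. RNA was extracted with an RNeasy kit and labelled with biotin, per the labels' protocols. The authors deposited array intensity values summarised with MAS5, per the submitters' processing notes, which give no version of it. MAS5 summarises the background-corrected intensities of a probe set as 1 signal. Whether the arrays were scaled to a target was not given in the sources used here, and MAS5 detection calls were not used here. GeneSpring GX 7.3.1 was used for normalization and analysis, per the series' design text, which names no test. Whether the deposited values hold a GeneSpring step was not given in the sources used here. The table held 22277 probe sets, 62 of them controls, and no column from outside the series. One probe set lacked values on 3 arrays and was left out.

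Gene names came from the platform table. Of 22215 probe sets apart from controls, 19064 were paired with 1 gene, 1043 with several and 2108 with none, and genes were named only from the first kind. Of the 19064, 19052 were found by gene ID in a RefSeq table (assembly GRCh38.p14), which changed 0 symbols and gave chromosomes and gene order only. A gene was represented by its tested one-gene probe set with the highest mean over all arrays. Of 792 called genes with a second tested probe set, 468 had one called the same way and 4 one called the other way, none of them among the 126 named genes. Of the called probe sets, 3031 had 1 gene and 356 did not. One planned single-gene value is not reported here.

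A pseudocount of 0.9, the 10th percentile of all values, was added before log2, so fold changes of dim genes are understated. Probe sets under the 40th percentile of the mean signal (7.453) were left out, which kept 13328 probe sets and 8067 genes. Limma 3.58.1 in R 4.3.3 fitted group alone (lmFit, eBayes with a variance trend, two-sided) with Benjamini-Hochberg adjustment over the probe sets tested, and "called" means an adjusted p under 0.05. Called, higher, lower, rose and fell refer to that test. Folds are 2 to the power of the log2 fold change.

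Each array's background level was the highest signal of 27 control probe sets for bacterial transcripts not spiked in, 7.1 to 12. Where an array of the lower group was at or under it, the fold is given as a bound: the bright group's mean over the lower group's mean, on the log scale, with each such value raised to the level. The bounds hold for each array's own level. The alternative with values raised to background uses the highest level of any array, 12, and gives lower folds for such genes (HAPLN1 had a log2 fold change of 5.67 there). The rule for bounds was extended to groups with 1 or 2 such arrays after the data were examined. Of the called genes, 60 higher ones were at background on all sensitive arrays and 51 lower ones on all resistant arrays.

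Gene lists, named genes and the alternatives were fixed before the data were examined, apart from 2 alternatives named in the closing section. The 30 lists hold 29 with at least 3 tested members. They were tested with limma's camera at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the 29. With an estimated correlation 0 lists were called and 2 had an unadjusted p under 0.05. Limma's fry, which tests whether a list's genes move on balance one way, called 16. Unlike camera, fry does not set a list's genes against the other genes tested, so its calls answer another question. Named genes were the AKR1C probe sets, the 12 largest rises and 12 largest falls by fitted fold change among genes called, changed at least 2-fold and not overlapping between groups, up to 4 called members of each list, every tested inner 5q14 gene, and the 2 brightest markers of each other cell type. Not every gene the rule takes is named in the text, and those left out are mostly ones whose call was lost in several fits without 1 array. Other members named as not called, and those that moved against their list, were chosen after their values were seen. Exact permutation tests of 3 against 3 arrays cannot go below p = 0.1.

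The labels give no batch, date or scan order, so none was tested. On simulated values with 100 probe sets changed by each of 2 sizes, the fit recovered 70% at a log2 change of 1 and 96% at 2, and 14 of 180 calls (7.78%) were false. The changed probe sets were drawn without the dimmest ones and were few among 13328, while 25.4% were called in the data. These shares therefore need not hold for the data, and the recovery does not cover the dimmest probe sets. For lists, 20 of 20 shifted ones were called higher at an adjusted p under 0.05, and 1 of 100 unshifted ones had an unadjusted p under 0.05. The simulated noise was independent between genes, while most real lists had a positive estimated correlation (0.145 for interferon genes). The simulation therefore does not show how often unshifted lists would be called in these data.

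Lists not described in the report were also tested. With the same counts adjusted over the list alone, of 12 p53 targets 2 were higher and 1 lower (camera adjusted p = 0.925), of 18 apoptosis regulators 2 and 2 (adjusted p = 0.925; median log2 fold change 0.0963, mean -0.0115 and camera's direction down), of 17 repair genes 3 and 2 (adjusted p = 0.756), and of 22 hypoxia and glycolysis genes 4 and 1 (adjusted p = 0.444). Of 11 inflammatory genes 3 were higher and 1 lower (3 and 4 adjusted over the list alone; adjusted p = 0.698). Of 20 ribosomal protein genes 4 were higher (3 adjusted over the list alone; adjusted p = 0.386, and 0.0478 with fry), and 2 were higher with values raised to background or without any 1 array but sensitive replicate 3. Of the p53 targets 1 was higher without replicates 1 or 2 of either group, and 2 were lower without sensitive replicate 1 and 0 without resistant replicate 3. Of the repair genes 1 was higher without sensitive replicates 1 or 2. Of the hypoxia genes 2 were lower without sensitive replicate 1 and 4 without resistant replicate 3. Of the inflammatory genes 2 were lower without sensitive replicate 1 and 4 without resistant replicate 1, and 1 was higher without resistant replicate 2.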

Results

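HT29 is an established human colon adenocarcinoma cell line, and methotrexate is an antifolate drug that blocks the making of nucleotides. Total RNA of methotrexate-sensitive HT29 cells and of methotrexate-resistant HT29 cells was measured on Affymetrix HG U133 A 2.0 arrays, with 3 arrays in each group and 6 in all. The labels give the methotrexate concentration of the resistant cells as 10e-5 M and none for the sensitive cells. They do not say whether the drug was present at harvest, so a response to the drug cannot be told apart from resistance. The median MAS5 signal of an array lay between 11.2 and 14.4, and 51.6% to 62.4% of its probe sets were above its background level. Over the 13328 probe sets tested, arrays of one group correlated with r between 0.964 and 0.970, and arrays of different groups with r between 0.908 and 0.918. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision of every value.

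Some array measures also separated the groups. The background level averaged 8.0 ± 1.01 on the sensitive and 10.6 ± 1.27 on the resistant arrays (SD, n = 3), and the GAPDH ratio of 3' to 5' control probe sets averaged 1.03 ± 0.0523 and 0.941 ± 0.010. For both, the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. The ACTB ratio of 3' to 5' control probe sets ranged from 1.42 to 2.36 and was highest on sensitive replicate 1. That array also had a signal of 3493 at the 5' control probe set of 18S ribosomal RNA, against 71.6 to 393.9 on the other arrays.

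The first comparison asked which transcripts differ between resistant and sensitive cells. AKR1C1, the aldo-keto reductase in the title of the series, rose 18.6-fold in the resistant cells, while IFI27, an interferon-induced gene, was 82.2-fold lower. Of 8067 genes tested, 1339 were higher and 861 were lower in the resistant cells, 2200 in all, and 5867 did not pass the test. Of the 2200, 987 had changed at least 2-fold, 624 upward and 363 downward. The 3 arrays of one group lay wholly apart from those of the other for 977 of these 987 genes. Over all tested genes that held for 3234, or 40.1%, where chance gives 10%. By probe set, 3387 of 13328 were called, 2029 higher and 1358 lower, and 1576 of them at least 2-fold, 976 higher and 600 lower. Over all calls, whatever their size, the direction of the balance depended on scaling. Higher calls made up 59.9% of the called probe sets as deposited and 47.5% after median centring, with 1723 higher and 1903 lower, and by gene 60.9% and 49.0%. Among probe sets changed at least 2-fold, higher ones stayed the majority after median centring, with 803 higher and 724 lower.

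By fitted fold change, the largest rises were led by HAPLN1, which encodes a link protein of the extracellular matrix. Its probe set was not above background on any sensitive array and averaged 615.2 ± 95.1 on the resistant arrays (SD, n = 3), at least 76.7-fold higher (adjusted p = 1.27e-15). CD99, a cell surface glycoprotein, rose 38.9-fold, from 26.4 ± 5.73 to 1048 ± 20.4 (adjusted p = 1.99e-14). HPN, a membrane serine protease, rose 29.2-fold (adjusted p = 1.95e-13). CLC, the Charcot-Leyden crystal protein, was at least 24.7-fold higher, APLP1 at least 14.7-fold, and the nuclear receptor NR0B2, whose probe set was at background on 2 of 3 sensitive arrays, at least 14.3-fold. The growth factor binding protein IGFBP7 was at least 12.6-fold higher, the chemokine receptor CXCR4 at least 12-fold, the tetraspanin CD37 at least 10.9-fold and the transcript LOC100996756 at least 10.1-fold. AKR1C2 and AKR1C1 completed the 12 largest rises by fitted fold change. Genes at background on the sensitive arrays have only a bound, so their place against measured genes such as AKR1B10 is not settled.

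Of the 12 largest falls by fitted fold change, 7 were members of the interferon list described below. BST2, another interferon-induced gene, fell from 1818 ± 329 to 8.47 ± 4.0 (SD, n = 3), at least 157-fold lower, with 2 of 3 resistant arrays at background (adjusted p = 6.32e-15). NNMT, nicotinamide N-methyltransferase, was at least 68.5-fold lower, with 2 of 3 resistant arrays at background. ITPKA, an inositol trisphosphate kinase, was at least 18.9-fold lower, again with 2 such arrays. INPP5D, an inositol phosphatase, was at least 11.6-fold lower and RARRES1, a retinoic acid responder, at least 8.39-fold lower, each at background on all 3 resistant arrays.

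The next comparison was that of the aldo-keto reductases, NADPH-dependent enzymes that reduce aldehydes and ketones. AKR1C1 rose from 256.4 ± 15.7 to 4793 ± 218 (SD, n = 3), a log2 fold change of 4.22 with SE 0.128 (adjusted p = 2.61e-15). Its other probe set rose 20.7-fold, from 192.3 ± 28.1 to 3972 ± 239. The 2 probe sets of AKR1C2 rose 25-fold and 22.9-fold, and that of AKR1C3 rose 5.64-fold, from 380.1 ± 30.1 to 2150 ± 225. AKR1B10, an aldo-keto reductase whose gene lies on another chromosome, rose 14.3-fold, from 57.8 ± 1.91 to 844.4 ± 100.2 (adjusted p = 1.02e-12). All 6 tested members of the list were higher, also adjusted over the list alone (5 or 6 with 1 array left out), with AKR7A3 at 1.62-fold and AKR7A2 at 1.32-fold. The list's median log2 fold change was 3.17 (camera adjusted p = 5.29e-10), and 1.60 to 3.23 under the 21 of 22 alternatives for lists in which it could be tested. With an estimated correlation the list was not called (adjusted p = 0.0668). The AKR1C genes are near-identical in sequence, so their probe sets may read each other's transcripts, and the values of the single genes are uncertain. The list test takes these 3 genes as separate members, so it may count 1 rise several times.

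**Figure D1:**
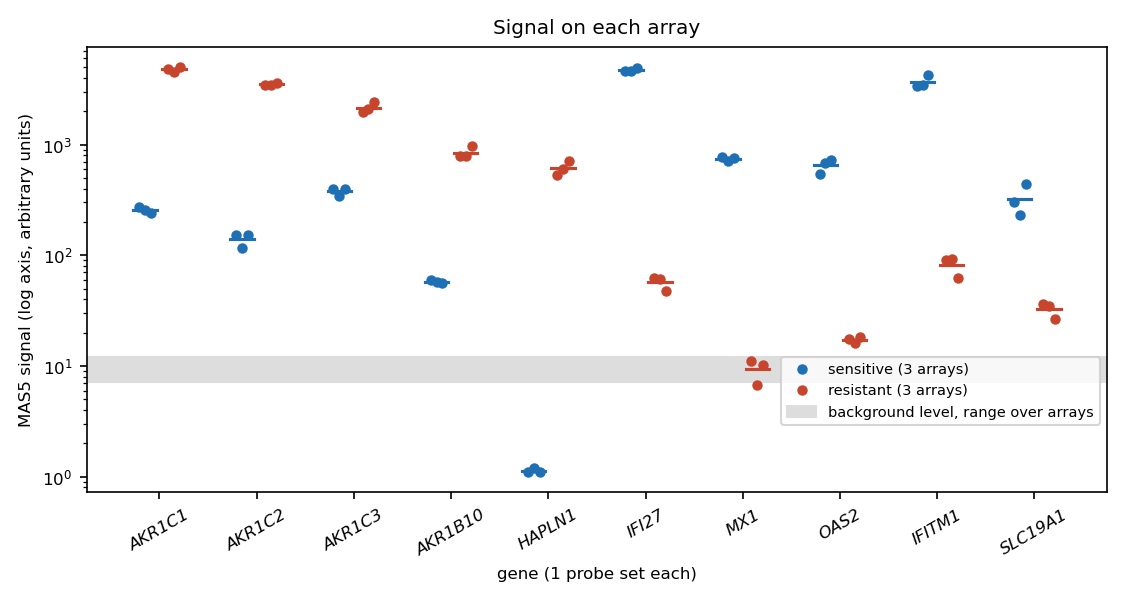
MAS5 signal (log axis, arbitrary units) of 10 genes on each of the 6 arrays, blue for sensitive and red for resistant, with a line at each group's mean and the range of background levels, 7.1 to 12, in grey. AKR1C1 lies near 256.4 on the sensitive and 4793 on the resistant arrays, and IFI27 near 4711 and 56.8.

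Genes of glutathione and drug metabolism were higher in part. Of 16 tested targets of the oxidative stress regulator NRF2, a list that holds no aldo-keto reductase, 8 rose and 8 did not pass (11 higher and 1 lower adjusted over the list alone). EPHX1, microsomal epoxide hydrolase, rose 2.27-fold, from 1522 ± 392 to 3401 ± 313 (SD, n = 3), and OSGIN1 rose 2.61-fold. The pentose phosphate enzyme PGD rose 2.12-fold and GCLC, the catalytic subunit of glutamate-cysteine ligase, 1.98-fold. NQO1, the NAD(P)H quinone reductase, was not called, at 1894 and 2166 (adjusted p = 0.244). The list's median log2 fold change was 0.672 (camera adjusted p = 0.000406; adjusted p = 0.498 with an estimated correlation). Of 13 phase II conjugation genes 6 rose and 7 did not pass, the same counts adjusted over the list alone. The glutathione transferase GSTA4 rose 5.72-fold, MGST3 2.51-fold and GSTO1 2.26-fold. The median was 0.752, or 0.683 with members at their bounds (camera adjusted p = 0.00330; adjusted p = 0.498 with an estimated correlation).

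The folate lists answer how the genes that carry and use folate differed. SLC19A1, the reduced folate carrier through which methotrexate enters cells, fell 9.47-fold in the resistant cells, from 324.7 ± 106.1 to 32.6 ± 5.34 (SD, n = 3; log2 fold change -3.24, SE 0.233, adjusted p = 1.47e-09), and its 2 other probe sets were 3.28-fold lower and at least 3.43-fold lower, the latter with 2 resistant arrays at background. With the mean of its probe sets the log2 fold change was -2.54. Of 8 tested transporters 3 were higher and 2 lower (4 and 2 adjusted over the list alone). The efflux pumps ABCC5 and ABCC1 were 2.00-fold and 1.45-fold higher, and the mitochondrial folate carrier SLC25A32 was 1.77-fold lower. The list's median log2 fold change was 0.307 while its mean was -0.194 and camera's direction was down (adjusted p = 0.876). Of 12 folate and one-carbon enzymes 4 rose and 8 did not pass, the same counts adjusted over the list alone. MTRR, methionine synthase reductase, rose 1.75-fold, TYMS, thymidylate synthase, 1.63-fold and AHCY 1.44-fold. This list was not called with camera (adjusted p = 0.286) and was with fry (0.0457). The count of higher enzymes fell to 2 without replicate 2 of either group. Among the transporters 1 was higher without sensitive replicates 1 or 2 and 0 without resistant replicates 2 or 3, and 1 was lower without sensitive replicates 2 or 3 or resistant replicates 1 or 2. With values raised to background 1 transporter was higher and 1 lower. The call of ABCC5 was lost without sensitive replicate 3 or resistant replicates 2 or 3 (adjusted p from 0.0543 to 0.145), that of ABCC1 without sensitive replicates 1 or 2 or resistant replicates 2 or 3 (0.0545 to 0.0961), that of SLC25A32 without sensitive replicates 2 or 3 or resistant replicates 1 or 2 (0.0646 to 0.174), and that of AHCY without replicate 2 of either group (0.0520 and 0.0777). The calls of ABCC5 and AHCY were also lost after median centring (adjusted p = 0.0792 and 0.0606), and that of ABCC1 with the mean of its probe sets (0.0843).

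Single genes of nucleotide synthesis changed in both directions, and neither list was called. Of 16 purine genes 5 were higher and 2 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.876). Without replicate 1 of either group 2 were higher and 0 lower, without replicate 2 of either group 3 and 0, and without resistant replicate 3 the counts were 3 and 2. With values raised to background 3 purine genes were higher and 1 lower. ADA, adenosine deaminase, rose from 12.4 ± 5.07 to 47.3 ± 4.50 (SD, n = 3), with 1 sensitive array at background, and IMPDH2, of guanine nucleotide synthesis, rose 1.53-fold. Of 18 pyrimidine and deoxynucleotide genes 5 were higher and 4 lower, likewise adjusted over the list alone, and 3 were higher without sensitive replicate 2, without any 1 of the resistant replicates or with values raised to background. The mitochondrial thymidine kinase TK2 rose 2.00-fold, while CTPS1, CTP synthase, fell 1.99-fold and RRM2, a subunit of ribonucleotide reductase, 1.92-fold. TYMP, thymidine phosphorylase, fell 3.40-fold, though its only probe set left when _x_at and _s_at probe sets were dropped gave a log2 fold change of 0.122 that was not called (adjusted p = 0.895, the highest of its 20 alternatives, which went down to 7.17e-09). The median log2 fold change was 0.163 and the mean -0.00702, with camera's direction down (adjusted p = 0.843).

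Interferon response genes were lower in the resistant cells throughout the list. All 26 tested members fell, also adjusted over the list alone (25 or 26 with 1 array left out), with a median log2 fold change of -2.35, or -2.28 with members at their bounds (camera adjusted p = 1.27e-43). With an estimated correlation the list was not called (adjusted p = 0.0520). IFI27 fell from 4711 ± 210.0 to 56.8 ± 8.49 (SD, n = 3), a log2 fold change of -6.36 with SE 0.158 (adjusted p = 1.47e-16). IFITM1, which restricts virus entry, fell 45.1-fold and the dynamin-like antiviral GTPases MX1 and MX2 were at least 67.1-fold and at least 20.8-fold lower. MX1 was at background on 1 and MX2 on all 3 resistant arrays. Among other large falls of the list, OASL fell 43.2-fold, OAS2 fell 35.5-fold and IFI44L was at least 9.65-fold lower. The smallest fitted fall was that of HLA-C, 1.94-fold, and RSAD2, at background on all 3 resistant arrays, was at least 1.59-fold lower. Of the array's own control probe sets, the one for the 3' end of ISGF3A averaged 287.5 ± 8.94 on the sensitive and 80.4 ± 17.8 on the resistant arrays (n = 3, exact permutation p = 0.1, the smallest possible).

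Replication genes were lower in part in the resistant cells. Of 22 tested genes of the G1/S transition and replication 10 fell, 1 rose and 11 did not pass, the same counts adjusted over the list alone, with a median log2 fold change of -0.570 (camera adjusted p = 0.000909; adjusted p = 0.498 with an estimated correlation). MCM4, of the replicative helicase, fell 3.61-fold, from 108.5 ± 13.5 to 29.9 ± 8.06 (SD, n = 3), CDC45 fell 2.59-fold and the transcription factor E2F1 1.96-fold. CCND1, cyclin D1, was the member that rose, by 1.58-fold, and 0 members were higher without sensitive replicate 2, without resistant replicate 3 or with values raised to background. Without sensitive replicate 3, 2 members were higher. The G2/M list was not called (camera adjusted p = 0.0816), with 1 member higher and 3 lower of 21 (the same adjusted over the list alone). The phosphatase CDC25B rose 2.46-fold, and UBE2C fell 1.94-fold, MKI67 1.59-fold and CCNB1 1.53-fold. Of the 3 other probe sets of MKI67 1 fell and 2 were not called, with log2 fold changes of 0.261 and -0.115, and with the mean of its probe sets the gene was not called (-0.381, adjusted p = 0.127). The call of MKI67 was also lost without resistant replicate 1 (adjusted p = 0.0570), and that of CCNB1 without replicates 1 or 2 of either group (0.0571 to 0.146). Without resistant replicate 1 only 1 member of the list was lower. The list was called after quantile normalization (adjusted p = 0.0479), with no filter on the mean (0.0292), with values raised to background (0.0439), with fry (0.0478) and without sensitive replicate 3 (0.0293).

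Differentiation genes of the intestine changed in opposite directions. Of 15 goblet cell and mucin genes 8 were higher, 2 lower and 5 not called, the same counts adjusted over the list alone. The gel-forming mucin MUC5AC rose 6.06-fold, from 100.1 ± 19.0 to 606.8 ± 79.1 (SD, n = 3), FCGBP was at least 4.30-fold higher with 1 sensitive array at background, and MUC5B, at background on all 3, at least 2.78-fold. Other probe sets of MUC5AC rose 6.38-fold and 2.68-fold, and another was not called (adjusted p = 0.0556). TFF2, a trefoil factor, was at least 4.36-fold lower with 1 resistant array at background. The median log2 fold change was 0.716, or 0.537 with members at their bounds (camera adjusted p = 0.0227; adjusted p = 0.523 with an estimated correlation). Only 1 of the list was lower without replicates 1 or 2 of either group or with values raised to background. The call was lost without resistant replicate 1 (median 0.682, adjusted p = 0.0698, where all alternatives ranged from 0.00822 to 0.523). Of 16 enterocyte genes 3 were higher and 3 lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.925). The peptidase ANPEP was at least 3.23-fold higher and DPP4 2.40-fold, and the adhesion molecule CEACAM1 fell 9.07-fold. Of 9 WNT target and crypt genes 4 were higher and 1 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.197, fry adjusted p = 0.0151), with DKK1 at 5.34-fold, CD44 at 4.0-fold, EPHB3 at 3.17-fold and PROM1 at 2.49-fold. The count of lower WNT target and crypt genes was 2 without sensitive replicate 3, 4 without resistant replicate 3 and 0 without any other array. Of the enterocyte genes 5 were higher without sensitive replicate 3. Only 2 enteroendocrine genes were tested, so that list had no test, and CCK, at background on all 3 resistant arrays, was at least 4.57-fold lower.

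Epithelial junction genes were lower in part. Of 19 tested 5 fell, 1 rose and 13 did not pass (7 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.298 (camera adjusted p = 0.00894; adjusted p = 0.523 with an estimated correlation). CDH1, E-cadherin, fell 2.27-fold, from 1506 ± 76.9 to 673.7 ± 154.2 (SD, n = 3), the transcription factor GRHL2 fell 2.66-fold and the splicing factor ESRP1 2.05-fold, while CLDN3, a claudin, rose 1.79-fold. The call of CLDN3 was lost with values raised to background (adjusted p = 0.0561), where 0 members were higher, and without a variance trend (0.0619). Without sensitive replicate 3, 2 members were higher and 5 lower, with a median of -0.197. Of 11 mesenchymal genes 4 were higher and 1 lower, likewise adjusted over the list alone, and the list was not called (camera adjusted p = 0.702). CAV1, caveolin, was at least 4.41-fold higher with 2 sensitive arrays at background, FN1, fibronectin, at background on all 3, at least 2.63-fold, with 4 of its 5 tested probe sets called higher, and TGFBI fell 2.10-fold.

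Genes of cholesterol and fatty acid synthesis were higher in part. Of 19 tested 12 rose, 1 fell and 6 did not pass (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.710 (camera adjusted p = 0.00330; adjusted p = 0.554 with an estimated correlation). LSS, lanosterol synthase, rose 3.16-fold, from 205.2 ± 44.4 to 641.5 ± 25.4 (SD, n = 3), DHCR7 rose 2.99-fold and SQLE, squalene epoxidase, 2.63-fold. The fatty acid enzymes FASN, ACACA and ACLY were not called, with log2 fold changes of -0.103, 0.0740 and 0.0177, and NSDHL, of sterol synthesis, was the member that fell, by 2.42-fold. Unfolded protein and amino acid stress genes were lower in part, with 7 of 22 lower and 1 higher (9 and 1 adjusted over the list alone) and a median of -0.326 (camera adjusted p = 0.0227; adjusted p = 0.554 with an estimated correlation). CHAC1, which degrades glutathione, fell 2.48-fold, PSAT1, of serine synthesis, 1.83-fold and PDIA4 1.53-fold, while HERPUD1 was the member that rose. The call of PDIA4 was lost without sensitive replicates 1 or 2 or resistant replicate 1 (adjusted p from 0.0582 to 0.0759). The count of lower genes was 3 with values raised to background and without sensitive replicate 1, 4 without resistant replicates 1 or 2 and 11 without resistant replicate 3, and 0 were higher with values raised to background or without any 1 array but sensitive replicate 3. The call of the list was lost without resistant replicate 1 (median -0.260, adjusted p = 0.0698, where all alternatives ranged from 0.00722 to 0.554).

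**Figure D2:**
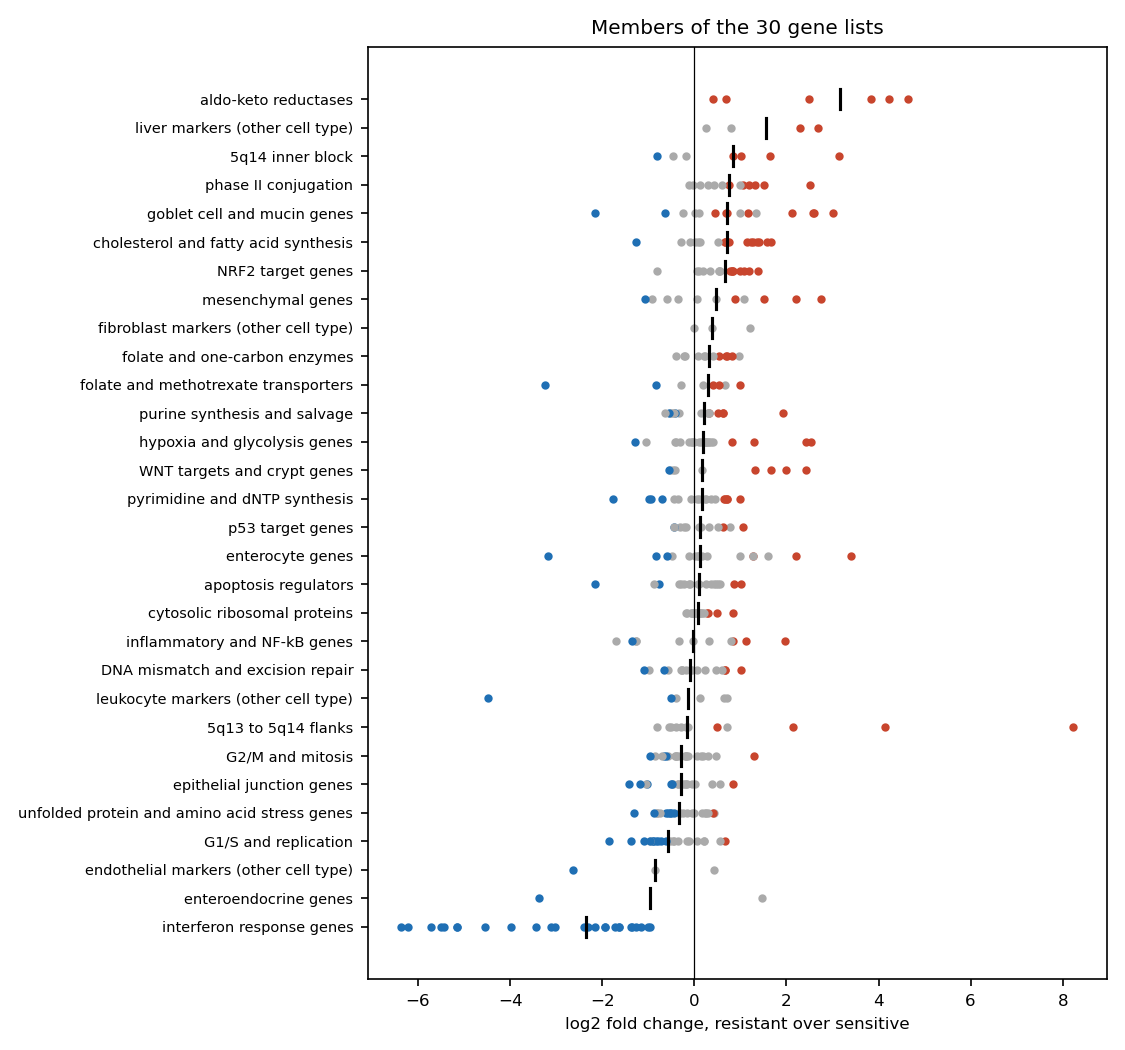
Log2 fold change of each tested member of the 30 gene lists, resistant over sensitive, 1 row per list, with red points for members called higher, blue for members called lower, grey for members not called, and a black line at the list's median. The median of the interferon response genes lies at -2.35 and that of the aldo-keto reductases at 3.17.

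A further comparison followed genes along chromosome 5, in 2 lists of neighbouring genes. Of the 8 tested genes from MSH3 to HAPLN1 in gene order, 7 rose and CKMT2 did not pass, with a median log2 fold change of 1.90. That median uses fitted values, also for genes at background. Of the other 11 tested genes from PDE8B to CCNH, COX7C was higher and SERINC5 lower, and their median was -0.403. The stretch from MSH3 to HAPLN1 is neither of the fixed lists. It takes in genes of both and starts and ends at genes called higher, so this contrast is descriptive only. SSBP2, a single-stranded DNA binding protein, rose 8.77-fold, from 19.1 ± 3.81 to 174.3 ± 34.1 (SD, n = 3, adjusted p = 1.76e-09), the ribosomal protein gene RPS23 rose 1.80-fold and MSH3, of mismatch repair, 2.02-fold. XRCC4, ATG10 and VCAN, at background on all 3 sensitive arrays, were at least 3.44-fold, at least 2.25-fold and at least 2.50-fold higher. Of 15 tested probe sets of the 8 genes 13 were called higher. The inner 5q14 list of 7 tested genes had 4 higher and 1 lower, also adjusted over the list alone, with a median of 0.851, and was not called (camera adjusted p = 0.151). THBS4 of this list was not called, with a log2 fold change of -0.472, and neither was CKMT2, whose fitted log2 fold change of -0.173 differed in sign from its means of 9.30 and 11.4. Leaving out 1 array moved the CKMT2 value between -0.713 and 0.844, and SERINC5 was 1.75-fold lower. Of the 7, 2 were higher without resistant replicates 1 or 3, and 0 were lower with values raised to background. The list was called without resistant replicate 2 (median 0.894, adjusted p = 0.0216, where all alternatives ranged up to 0.743). The flanking list of 12 had 4 higher, also adjusted over the list alone, with a median of -0.156 and a mean of 1.07, with camera's direction up, and was not called (camera adjusted p = 0.386). The call of MSH3 was lost without replicates 1 or 2 of the sensitive or 1 or 3 of the resistant group (adjusted p from 0.0617 to 0.147), that of ATG10 without resistant replicates 1 or 3 (0.0841 and 0.0924), and that of VCAN without resistant replicate 3 (0.0666). With all values raised to the highest background level, 12, the log2 fold changes of XRCC4, ATG10 and VCAN were 1.19, 0.580 and 0.727, and ATG10 was not called (adjusted p = 0.134).

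**Figure D3:**
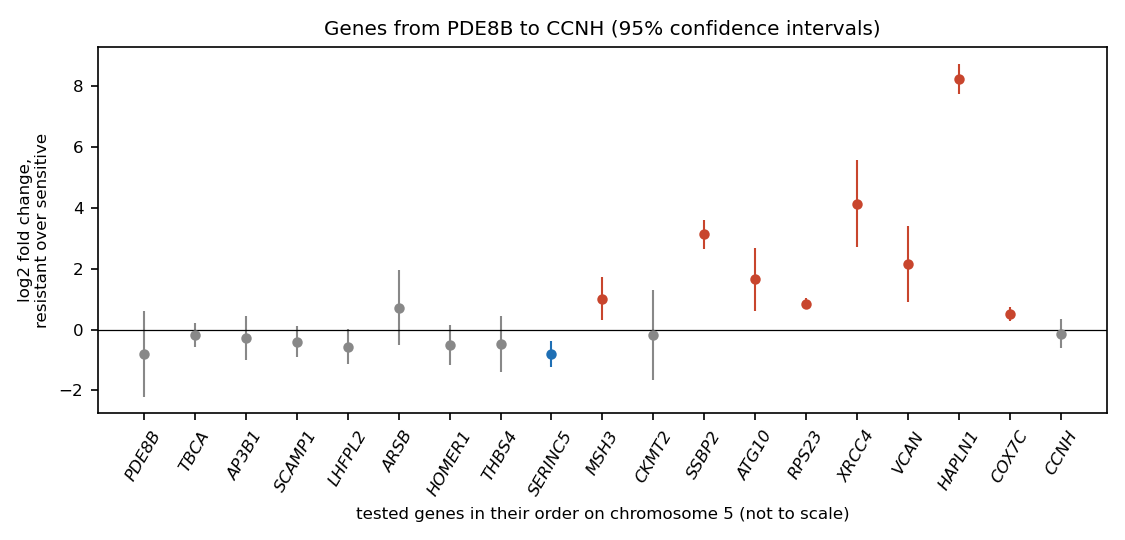
Log2 fold change, resistant over sensitive, with 95% confidence intervals, of the 19 tested genes from PDE8B to CCNH in their order on chromosome 5 (not to scale), red for called higher, blue for called lower and grey for not called. From MSH3 to HAPLN1, a stretch that is neither of the fixed lists, 7 of 8 genes are red, and of the other 11 genes 1 is red and 1 blue.

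Of the other cell types that a culture could hold, no list of markers was called with camera, while fry called the liver markers (adjusted p = 6.02e-05) and the fibroblast markers (0.0279). Of 6 leukocyte markers 2 were lower, also adjusted over the list alone (camera adjusted p = 0.197). LYZ, lysozyme, was 1.42-fold lower, not called without resistant replicate 2 (adjusted p = 0.0615), and CD14, a co-receptor for bacterial lipopolysaccharide, fell from 136.4 ± 31.5 to 6.03 ± 4.52 (SD, n = 3), at least 12.7-fold. None of the 3 fibroblast markers was called by the probe set that represents it, with COL1A1 at 43.3 and 45.2 and THY1 at 11.2 and 14.7 (camera adjusted p = 0.843). Of the 2 other probe sets of COL1A1 1 was called, at least 2.14-fold higher and at background on all 3 sensitive arrays (adjusted p = 0.00479), and 1 was not. Of 3 endothelial markers ENG was at least 3.00-fold lower, with 2 resistant arrays at background, and ROBO4 was not called, at 7.13 and 11.1 (camera adjusted p = 0.373). Of 4 liver markers 2 were higher, also adjusted over the list alone (camera adjusted p = 0.0816), among them TTR, transthyretin, at least 6.24-fold with 2 sensitive arrays at background, while SERPINA1 was not called, at 1680 and 1993. Without sensitive replicate 3 SERPINA1 was called (adjusted p = 0.0128), without any 1 of the resistant replicates only 1 liver marker was higher, and without sensitive replicate 1 the liver list was (0.0477).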

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

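The tests with values raised to the background level, and those restricted to probe sets measured on all arrays of 1 group, were chosen after seeing the data. AKR1C1 stayed called and higher under each of its 19 alternatives, with log2 fold changes from 4.12 to 4.30. It has no probe set left when _x_at and _s_at probe sets are dropped. Of 2437 values of the other 125 named genes under 20 alternatives, 2268 kept their side of the threshold, 166 lost the call and 2 gained one. The remaining 1 was a called gene that reversed: TYMP gave 0.122 without _x_at and _s_at probe sets. Changes of sign in a gene called in neither fit count among the 2268, as for CKMT2, whose values ran from -1.06 to 0.844. With 1 array left out, called probe sets ranged from 2513 to 3431, those changed at least 2-fold from 1477 to 1634, called genes from 1611 to 2248 and called lists from 7 to 10. Without a variance trend 2243 probe sets and 1455 genes were called, and the cause was not tested. Dropping _x_at and _s_at probe sets, which leaves fewer to test, gave 1490 probe sets, 755 at least 2-fold, 1229 genes and 4 lists. Testing against a fold of 1.5 (limma's treat) called 886 probe sets, against 1576 called and changed at least 2-fold. The replicate numbers did not pair the arrays: same-numbered deviations correlated at -0.0215, -0.024 and -0.139, and 0 of 6 arrays correlated best with their own number. With replicate number as a block 3232 probe sets were called. With values raised to the highest background level of any array 2572 probe sets were called and in the measured set 3553. Scaling moved the median of all log2 fold changes from 0.0587 to -0.0135 (quantile) and -0.0403 (median centring). For lists, an estimated correlation called 0 (2 at an unadjusted p under 0.05) and fry 16. The adjusted p with an estimated correlation was 0.0520 for interferon genes (median -2.35), 0.0668 for aldo-keto reductases (3.17), 0.498 for NRF2 targets (0.672), phase II genes (0.752) and G1/S genes (-0.570), 0.523 for goblet genes (0.716) and junction genes (-0.298), and 0.554 for stress genes (-0.326) and cholesterol genes (0.710). Goblet genes also lost the call with the 60th percentile filter (0.574), without _x_at and _s_at probe sets (0.716), with the mean of a gene's probe sets (0.716) and with values raised to background (0.456), and without resistant replicate 1, with medians from 0.477 to 0.828 over the arrays left out. Stress genes lost it with the 60th percentile filter (-0.240), without _x_at and _s_at probe sets (-0.289), with fry (-0.326) and without resistant replicate 1 (-0.457 to -0.260). Without _x_at and _s_at probe sets junction genes (-0.297) and cholesterol genes (0.631) lost it. The inner 5q14 list gained a call with fry (0.851), in the measured set (1.02) and without resistant replicate 2 (0.810 to 0.894). The flanking list gained one with fry, whose direction was up (mean 1.07, though the median was -0.156). Fry also called the folate enzymes, WNT and crypt genes and ribosomal proteins. Since fry does not set a list against the other genes, its calls do not show that a list changed more than they did. The cause of the other gains and losses was not tested. Leaving 1 member out of the inner 5q14 list was not run, since it would leave its tested genes as they were. Signals near the background level of 7.1 to 12 limit which dim genes can be read.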

Other observations

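The tests of leukocyte genes and those of the aldo-keto reductase pattern were chosen only after the result was seen, as was the reading of windows other than that on chromosome 5. Single genes of other lists changed, while the lists themselves were not called with camera. Of these lists fry called the ribosomal proteins (adjusted p = 0.0478). Of the glycolysis genes ENO2, neuronal enolase, rose 5.83-fold, from 38.5 ± 8.40 to 227.5 ± 35.2 (SD, n = 3), and ALDOC, aldolase C, 5.34-fold, while PKM fell 2.45-fold. The other tested probe set of PKM, dimmer at 19.6 and 18.3, was not called (log2 fold change -0.0795, adjusted p = 0.906). LCN2, lipocalin 2, fell 2.56-fold, from 7635 ± 561 to 2984 ± 194, while NFKBIA rose 1.80-fold. PMAIP1, a pro-apoptotic p53 target, was at least 2.31-fold lower, at background on all 3 resistant arrays, and BCL2L1 and BAD rose 1.82-fold and 2.01-fold. TP53I3, another p53 target, rose 2.08-fold. Of repair genes LIG1 fell 2.15-fold, UNG fell 1.58-fold and ERCC1 rose 1.58-fold. The ribosomal protein gene RPL3 rose 1.41-fold.

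Windows of 7 neighbouring tested genes were scanned by their median moderated t, against 1000 shuffles of the genes. A window on chromosome 10, from PDZD7 to NPM3, was high (median log2 fold change 1.60, with a median t reached in 23 shuffles). On chromosome 19 the window from KCTD15 to FXYD5, which holds HPN, was high as well (median 1.18, 24 shuffles). A window at one end of the X chromosome, from PLCXD1 to CD99, was also high (median 1.21, 35 shuffles). At the other end of X the window from DNASE1L1 to SLC10A3 was low (median -1.22, 9 shuffles), as was the one from HTATSF1 to EOLA2 (median -1.49, 8 shuffles). A low window on chromosome 11 held the interferon-induced IFITM1, IFITM2 and IFITM3 (median -2.01, 2 shuffles).

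The fall of the interferon genes was weighed against measurement and mixture. If scaling or dim noise had caused it, the list's median should approach 0 under other scalings, but the highest median under quantile normalization, median centring and the background floor was -2.318. Leukocytes mixed into the sensitive cultures should bring their abundant transcripts, but of PTPRC, HLA-DRA and CD74 only 1, CD74, was above background on all 3 sensitive arrays, which argues against leukocytes as the whole cause. A small share stays open, since CD14 fell with the interferon genes. A lasting difference in interferon signalling between the cell populations may be a biological explanation, as a hypothesis, and was not tested.

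The rise of AKR1C1, AKR1C2 and AKR1C3 was weighed against 3 explanations. A gain of the surrounding segment of chromosome 10 should raise the neighbours, but the 10 nearest tested genes had a median log2 fold change of -0.0558, with 2 called higher, TUBAL3 (1.75, adjusted p = 0.0389) and IDI1 (0.718, 0.0433). This argues against a gain that takes in those neighbours, and a narrower one was not tested. Whether 1 risen transcript read by all the probe sets could account for the pattern stays open. AKR1C3 rose by less than AKR1C1, by -1.726 on the log2 scale, which partial cross-hybridisation would also give. The AKR1C3 probe set has neither an _x_at nor an _s_at suffix, and AKR1C3 kept its call in all 20 alternatives. All tested probe sets of AKR1C1 and AKR1C2 are _x_at. The suffix alone does not settle what the AKR1C3 probe set reads. A shared rise of NRF2 targets stays open too, since the list's adjusted p of 0.000406 became 0.4977 with an estimated correlation.

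The rise of neighbouring genes on chromosome 5 was weighed against noise and chance. With values raised to the background level 6 genes from MSH3 to HAPLN1 stayed higher. SSBP2 and RPS23 among them were above background on every sensitive array, which argues against noise of dim signals as the whole cause. XRCC4, VCAN and HAPLN1 were at background on all sensitive arrays. For them the floor sets those arrays to the same value and removes their spread, so their calls cannot decide the question. Chance clustering in a search of all chromosomes may account for it. In 342 of 1000 shuffles some window of 7 genes reached a median t as high as that from CKMT2 to HAPLN1. In 1000 shuffles one reached that of the window from MSH3 to VCAN. Among 7924 windows these ranked 19 and 145. How often chance would give such a window in a region fixed beforehand was not tested. A gain of the segment is a biological hypothesis that these shuffles do not separate from chance.

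The count of 3387 probe sets was set against the other splits of the 6 arrays into 3 and 3. Of the 10 splits 1, the real one, gave as many. The highest of the others gave 0 with limma, and at most 601 at an unadjusted p under 0.05. Each of those splits mixes both groups on each side, so differences between the groups enlarge its spread and hold its count down. The 0 is therefore no measure of chance. With 10 splits the share cannot fall under 0.05, so the design is too small for this test to say more.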
